A study of Mus musculus with 8 samples.

How the data were processed

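Two-colour Agilent expression arrays of mouse footpad skin were analysed, 8 arrays in 4 groups of 2: wild type and Dkk4 transgenic at E15.5 and at E16.5. Groups and replicate numbers were taken from the labels. Per the labels' protocols, Cy3 carried footpad RNA extracted with Trizol and Cy5 a reference of pooled mouse cell line RNA and embryonic stem cell RNA, both amplified and labelled with a linear amplification kit. No dyes were swapped, so a dye bias of single probes stays in every ratio and drops out of differences between groups.

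The deposited scanner files hold, per the file headers, spot intensities extracted with Agilent Feature Extraction 9.5.1.1 under a 2-colour protocol, as mean pixel intensity and median local background intensity of each channel, with Agilent's processed signals, its log10 ratio and flags beside them. Each array had 43451 spots, of which 1417 were controls, and 42034 spots for 42006 probes of 60 bases; 7 probes had 5 spots each and the others 1. The headers name the mouse build mm7, and positions were not used here. The deposited series table holds 25030 probes with the authors' processed values, whose scale, centring and direction are not given in the sources used here. Set against the scanner values, they followed log10 of the Cy3 processed signal (correlation 0.9941 to 0.9969 per array) and not the ratio (0.215 to 0.248), with column medians of 2.569 to 2.575; how the authors centred the arrays and adjusted single probes stays unknown. This table was used as an alternative.

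Background was corrected with normexp (offset 50) on the mean and background intensities, and log ratios were normalized within each array by loess with control spots at weight 0, in limma 3.58.1 (R 4.3.3). Ratios were turned to sample over reference. The 69 spots flagged as outliers over all arrays were left out, spots of a probe were averaged, and probes were kept where Cy3 was well above background on both arrays of at least 1 group, which left 31627. The offset pulls the ratio of a dim spot towards 0, which shrinks a difference between dim spots and can enlarge one between bright spots and spots that are dim in both channels. No spot other than controls was saturated in Cy3 (0), and 3 to 11 spots per array were saturated in Cy5. One linear model with 4 group means was fitted to all arrays (4 residual degrees of freedom, with a prior of 4.22), so that all groups shared one estimate of the spread. Moderated tests from eBayes were two-sided, with Benjamini-Hochberg adjustment over the probes tested in each comparison and a threshold of 0.05. One probe lacked a value on both arrays of a group, so comparisons with E15.5 wild type had 31626 probes. Each channel was also tested alone after quantile normalization between arrays.

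The gene name, systematic name and probe name fields were the same for all probes, and 0 of 42006 identifiers occurred in the RefSeq gene table of assembly GRCm38.p6 used here. For this reason the planned gene lists, the pathway genes and the Dkk4 transcript could not be looked up by name, and probe sequences were not matched to transcripts here. The choice of 1 probe per gene had no effect, and every result is per probe. The planned rule for named genes, which asked for gene symbols, was replaced once the fields proved to hold none: in each comparison the text names up to 2 probes with the largest rise and 2 with the largest fall among those past the threshold whose groups did not overlap. For the averaged comparison the groups had to be separate in the same direction at both ages, and for the difference between ages they had to be separate at E16.5. Probes named outside this rule are said to have been chosen after their values were seen.

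Slide, position and scan day were read from the file headers. Slide 1 held the 4 E15.5 arrays, slide 2 the transgenic E16.5 arrays and slide 3 the wild-type E16.5 arrays, each with its own scan day. Transgenic arrays were at positions 1 and 2 and wild-type arrays at positions 3 and 4 throughout. No group spanned 2 slides, so a random slide effect could not be estimated, and the within-slide fit at E15.5 is that on the 4 arrays of this age.

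The fit was tested on simulated log ratios for 31627 probes with the estimated spread and 200 changed probes, 50 of each size; 36% of the 50 with the smallest change, 0.32 log2 units, were recovered at either age. For E15.5 it recovered 96%, 100% and 98% of probes changed 1.5-, 2- and 4-fold, and 11 of 176 calls were false. For E16.5 it recovered 80%, 96% and 100%, and 6 of 162 calls were false. The simulations shared means, spread and model and differed in the random draw and in the group that carried the change. Their recovery therefore does not show that either age had the better power. Nor does it give the power of the real E15.5 comparison, where far fewer probes were called and the adjustment was stricter.

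Alternatives set before the data were examined were no background correction, Agilent's processed signals, median centring, the Cy3 channel alone, no filter and a stricter filter, a 2-fold minimum, eBayes with a trend and robust prior, fits on the 4 arrays compared, the replicate number as a block, the series table and leaving out each array. Added later were fits without probes whose Cy5 signal differed, with a loess on probe GC content and on the probes of the series table. Protein motifs were searched in the 3 forward reading frames of the tested probes. The 13 motif classes were written down before their fold changes were looked at. The 3 classes with at least 5 tested probes were tested with camera (preset correlation 0.01). A homeodomain class, also planned, had 3. A second planned set test, fry, asks whether the probes of a set change at all, without comparing them with the other probes.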

Results

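Footpad skin was taken from mouse embryos of 2 genotypes, wild type and a line that carries a skin-specific Dkk4 transgene, at embryonic stages E15.5 and E16.5. Dkk4 is a secreted inhibitor of Wnt signalling. Footpads are where mouse sweat glands form, and the series title places the arrays in a study of the Wnt, Eda and Shh pathways in sweat gland development. Each of the 4 groups held 2 arrays, 8 in all. Sample RNA was labelled with Cy3 and hybridised together with one common Cy5 reference, a pool of RNA from mouse cell lines mixed with embryonic stem cell RNA. Levels are therefore given as log2 of the sample signal over the reference signal.

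The files pair no probe with a gene name. The gene name field differed from the probe identifier for 0 of 42006 probes, and 0 identifiers were found in the RefSeq table used here. Results are given per probe, with at most 2 probes that rose and 2 that fell in each comparison, and the level of the Dkk4 transcript itself was not analysed here. Of the 42006 probes, 31627 (75.3%) had a sample signal well above background on both arrays of at least 1 group and were tested. The share of spots with Cy3 well above background was lowest, at 67.1%, on wild-type E16.5 replicate 2 and highest, at 77.2%, on transgenic E16.5 replicate 2. Replicate arrays correlated at 0.9946 to 0.9954 over the tested probes. The leading principal component (62.2% of the variance) separated the ages, and the next (18%) the genotypes at E16.5. The median SD between replicates ran from 0.039 log2 units in transgenic E16.5 to 0.046 in wild-type E16.5. The labels do not say whether replicates came from separate animals or litters, so p-values measure only the spread between these samples. The 2 arrays per group limit the precision of each value.

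The first comparison asked which transcripts differed between Dkk4 transgenic and wild-type footpad skin at E15.5. A single probe, Z00022557-1, passed the threshold, and it was lower in the transgenic skin. Its sequence was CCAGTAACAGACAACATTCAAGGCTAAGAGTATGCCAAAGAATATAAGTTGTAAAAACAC. Its Cy3 signal was 15900 and 13500 on the wild-type arrays and 27.9 and 46.2 on the transgenic arrays. The mean log2 ratio was 3.64 ± 0.06 (SD, n = 2) in wild type and 0.33 ± 0.08 (SD, n = 2) in transgenic skin, a log2 difference of -3.31 (SE 0.08, limma adjusted p = 1.92e-06). The Cy5 signal of this probe fell too, from 1320 and 1030 to 3.09 and 6.11, where it was not well above background. With the sample channel alone the log2 difference was -6.16, and with Agilent's own processed signals it was -0.61 (adjusted p = 0.614, the highest over the alternatives). The call was lost in 2 of 20 alternatives, with these signals and with the series table (-1.81, adjusted p = 0.586). Without background correction the difference was -3.24. There, as with the offset, the ratio of a spot dim in both channels is pulled towards 0, so this value is no independent support. The size of -3.31 depends on how such dim spots are treated. With the settings used throughout, limma called no probe higher in transgenic skin: 0 of 31626 probes tested, with 2385 at an unadjusted p under 0.05 in either direction. The largest rise in which both transgenic arrays lay above both wild-type arrays was 1.32 on the log2 scale, at Z00075231-1 (SE 0.65, adjusted p = 0.716), a probe chosen after its values were seen. The groups did not overlap for 36.8% of all probes, against 33.3% by chance. In data simulated for this comparison, 96% of probes changed 1.5-fold were recovered among 31627 probes, 200 of which were changed. So many changed probes make the adjustment more lenient than in the real comparison, which had 1 call. The recovery therefore does not show that a 1.5-fold change would have been called here. Z00060082-1, chosen after its values were seen, differed by -0.56 (1.47-fold, SE 0.07) at E15.5 and was not called (limma adjusted p = 0.305). All 4 arrays of this age shared 1 slide and 1 scan day, with the transgenic arrays at positions 1 and 2. Median centring in place of loess gave 52 calls at E15.5, with 1 common spread for all probes, and the count was 6 without transgenic replicate 2 and 2 without wild-type replicate 1. Of these calls 30, 3 and 1 were higher in transgenic skin, as were 4 with the trend and robust prior and 1 with Cy3 alone.

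**Figure D1:**
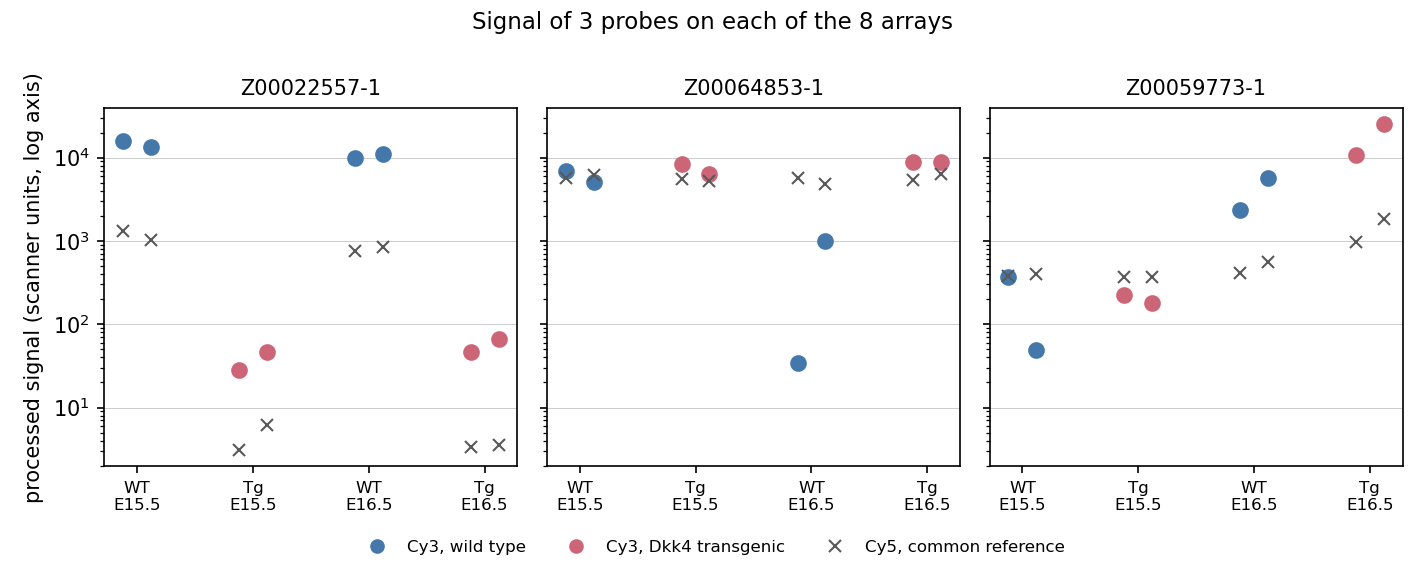
Processed signals, on a log axis, of 3 probes on each of the 8 arrays, with circles for the Cy3 sample channel and crosses for the Cy5 reference channel. Probe Z00022557-1 was low on all 4 transgenic arrays in both channels, Z00064853-1 was low in Cy3 on the wild-type E16.5 arrays alone (34 and 1010), and Z00059773-1 was higher at E16.5 than at E15.5 in both genotypes.

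The second comparison asked the same question at E16.5. Here 4364 of 31627 probes (13.8%) differed, 2316 higher and 2048 lower in transgenic skin. Most differences were small: the median size of a called change was 0.27 log2 units, and 96% of the called probes changed by less than 1.5-fold. At least 2-fold differences were found for 25 of them, 20 of these higher in transgenic skin. The groups did not overlap for 61.1% of all probes, against 33.3% by chance. Z00064853-1 rose most, by 4.27 on the log2 scale (SE 0.77, adjusted p = 0.0142), with a mean log2 ratio of -3.55 ± 2.15 (SD, n = 2) in wild type and 0.71 ± 0.16 (SD, n = 2) in transgenic skin. The wild-type arrays were far apart, at -5.07 and -2.03, and the rise was 2.75 or 5.78 without one of them. The call was lost in 4 of 20 alternatives: Agilent's signals (adjusted p = 0.0941, the highest), the trend and robust prior (adjusted p = 0.0696) and without either transgenic array. Z00025402-1 followed with a rise of 3.98 (SE 0.82, adjusted p = 0.0207), from -4.85 and -1.61 on the wild-type arrays to 0.89 and 0.59 on the transgenic ones. Its Cy3 signal was well above background on 1 of the 2 wild-type arrays, and its rise was 2.36 without replicate 1 and 5.59 without replicate 2 of wild type. Its call was lost in 6 of 21 alternatives (highest adjusted p = 0.121). Both probes also stood lower in wild type at E16.5 than at E15.5. Z00022557-1 fell by 3.11 (SE 0.08, adjusted p = 3.16e-06), the largest called fall, with Cy3 signals of 9840 and 11200 in wild type and 46.4 and 67.3 in transgenic skin. Agilent's processed ratio reversed the sign of this probe at E16.5, to 0.30 (adjusted p = 0.268, the highest over the alternatives), and the series table, at -1.22 (adjusted p = 0.0571), also ended the call, while the sample channel alone gave -5.99. Z00016441-1 fell by 1.57 (SE 0.41, adjusted p = 0.0422), with log2 ratios of 2.64 and 2.41 in wild type against 0.51 and 1.39 in transgenic skin. This call was lost in 8 of 22 alternatives, among them leaving out any of the 4 arrays (log2 differences of -2.01 to -1.13, highest adjusted p = 0.164). The reference channel tested alone called 46 probes at this age.

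At E16.5 the transgenic arrays lay on one slide and the wild-type arrays on another, each with its own scan day, so slide and genotype cannot be told apart. The count fell when any of the 4 arrays was left out, and also when an E15.5 array, which is not compared here, was left out. With fewer arrays the spread is estimated less well, so the fall is not due to the left-out array alone. The count was 1437 with Agilent's processed signals, and with median centring the share of calls that were higher moved from 53.1% to 94.9%.

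**Figure D2:**
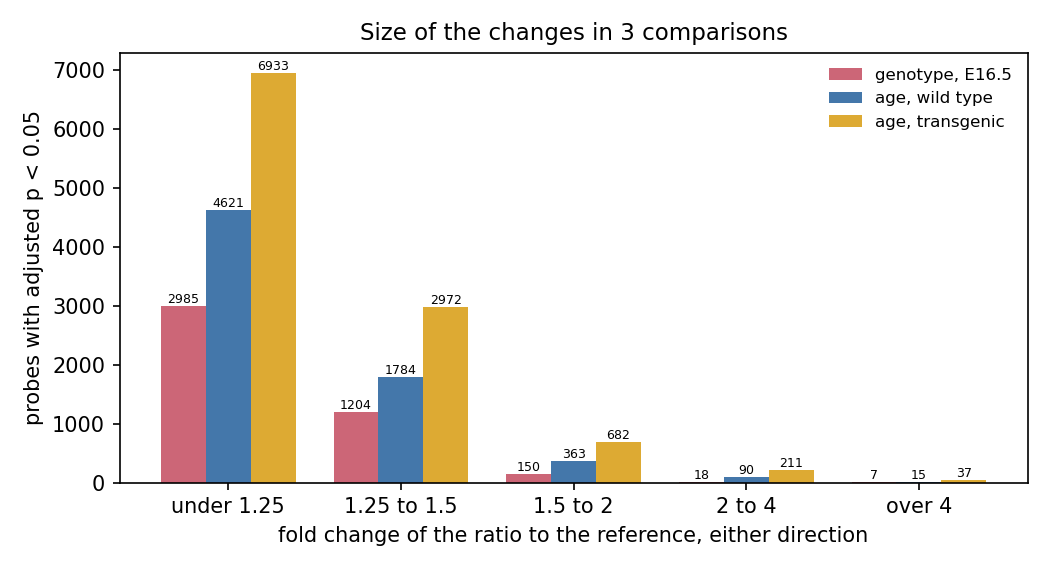
Number of probes with adjusted p < 0.05 in each class of fold change, in either direction, for the genotype comparison at E16.5 and for the age comparison in wild-type and in transgenic skin. The classes under 1.5-fold held 96% of the genotype calls, 93.2% of the wild-type age calls and 91.4% of the transgenic age calls.

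Averaged over both ages, 1566 probes differed between the genotypes, 1156 higher and 410 lower in transgenic skin, and 6 of them by at least 2-fold. Of these calls, 1456 (93%) were also called at E16.5. Among called probes whose groups did not overlap at either age, Z00064860-1 showed the largest mean rise, 1.59 (SE 0.18, adjusted p = 0.00548). Its log2 ratio was 1.97 ± 0.20 in transgenic and 1.27 ± 0.30 in wild-type skin at E15.5, and 1.56 ± 0.23 against -0.92 ± 0.56 at E16.5 (SD, n = 2 each). Z00002110-1 rose by 1.33 (SE 0.18, adjusted p = 0.00947), and most of this lay at E16.5 as well, where its log2 ratio was 1.16 in transgenic and -1.16 in wild-type skin. Cy3 of both probes was well above background on 1 of the 2 wild-type E16.5 arrays. Z00022557-1 fell by 3.21 (SE 0.05, adjusted p = 1.43e-07). Z00060082-1 fell by 0.83 (SE 0.05, adjusted p = 0.00242), from 1.22 to 0.67 at E15.5 and from 1.90 to 0.80 at E16.5. In the order named, these calls were lost by adjusted p in 1 of 18, 3 of 20, 2 of 19 and 1 of 20 alternatives. Agilent's processed signals were among them for each, with differences of 2.43, 2.51, -0.15 and -1.54. The 2-fold minimum also leaves out Z00060082-1, which these numbers do not count. No probe (0) was at least 2-fold higher in transgenic skin at both ages with groups that did not overlap at either age. The log2 differences at the 2 ages, which share no array, correlated at 0.18 across probes, and at 0.16 without Z00022557-1; probes are not independent replicates. Of the 4364 probes called at E16.5, 63.1% had the same sign at E15.5, against 51.7% of the probes not called. The averaged count was 1248 without wild-type E16.5 replicate 1 and between 389 and 1019 without any other single array, and Agilent's processed signals gave 152.

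The test of whether the transgenic effect itself differed between the ages called 29 probes, 20 with a more positive effect at E16.5 and 9 with a more negative one, and 5989 had an unadjusted p under 0.05. In Z00067181-1 the log2 difference between transgenic and wild type was -0.16 at E15.5 and 0.90 at E16.5, an increase of 1.06 (SE 0.12, adjusted p = 0.0454). Its Cy5 signal was well above background on 0 of the 4 wild-type arrays and 1 of the 2 transgenic E16.5 arrays, so the size is imprecise: 0.72 with the sample channel alone and 2.31 with Agilent's signals. In Z00066250-1 it was -0.29 and 0.48, an increase of 0.77 (SE 0.09, adjusted p = 0.0455). Z00054050-1 went the other way, from 0.29 to -0.77, a change of -1.06 (SE 0.13, adjusted p = 0.0455), as did Z00032151-1, from 0.39 to -0.66, a change of -1.05 (SE 0.12, adjusted p = 0.0454). At E16.5 the lower ratio of Z00032151-1 lay mostly in the reference channel: the difference was -0.20 with Cy3 alone and 0.50 with Cy5 alone. All 4 adjusted p-values lay close to the threshold, and the count was 0 with the sample channel alone, with no filter on dim probes or with a correction for probe GC content. Without single arrays it ran from 0 to 103, and leaving out any of the 8 moved it by over 1.5 times. Since the E16.5 genotypes lay on different slides, slide enters this difference too.

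The last comparisons followed each genotype from E15.5 to E16.5. In wild-type skin 6873 of 31626 probes (21.7%) changed, 3284 upwards and 3589 downwards, and in transgenic skin 10835 of 31627 (34.3%), 5151 upwards and 5684 downwards. At least 2-fold changes were found for 105 probes in wild type and for 248 in transgenic skin, 221 of the latter upwards. The same 2 probes rose most in both. Z00059773-1 rose by 3.53 (SE 0.45, adjusted p = 0.00239) in wild type and by 4.18 (SE 0.45, adjusted p = 0.000662) in transgenic skin, where its Cy3 signal went from 227 and 180 to 10900 and 25200. Z00041156-1 rose by 3.49 (SE 0.46, adjusted p = 0.00273) and by 3.87 (SE 0.46, adjusted p = 0.000934). The wild-type E15.5 arrays lay apart, at 0.05 and -1.48 for Z00059773-1 and -0.06 and -1.72 for Z00041156-1. Without replicate 1 of that group the wild-type rises were 4.30 and 4.32. Over the alternatives they ran from 2.76 to 4.42 and from 2.66 to 4.32. These probes share 40 bases of their sequences, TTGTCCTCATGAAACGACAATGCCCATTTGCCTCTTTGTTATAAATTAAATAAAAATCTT for Z00059773-1 and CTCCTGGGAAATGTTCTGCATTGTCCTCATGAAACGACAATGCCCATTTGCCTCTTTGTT for Z00041156-1, so they are no independent measurements. Their Cy5 signals rose as well, by 1.72 and 2.20 log2 units in the transgenic comparison, where Cy3 alone rose by 5.49 and 5.62. Tested alone, the reference channel called 532 probes in the transgenic age comparison and 35 in the wild-type one.

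In wild type Z00064853-1 fell by 3.68 (SE 0.77, adjusted p = 0.0139) and Z00025402-1 fell by 3.48 (SE 0.82, adjusted p = 0.0209). Their sizes and rank rest on wild-type E16.5 replicate 1, where Cy3 was 34 and 19.1, the latter not well above background: without it the changes were -2.16 and -1.87, and without replicate 2 they were -5.20 and -5.10. These calls were lost in 4 of 20 and 5 of 21 alternatives (highest adjusted p = 0.0909 and 0.116). In transgenic skin Z00064853-1 changed by 0.16 (SE 0.77, adjusted p = 0.892). There Z00047077-1 had the largest called fall: it fell by 2.30 (SE 0.30, adjusted p = 0.00121), and in wild type it fell by 3.07 (SE 0.30, adjusted p = 0.000821). Z00063695-1 fell by 1.30 (SE 0.05, adjusted p = 5.74e-05) in transgenic skin and in wild type it fell by 1.88 (SE 0.05, adjusted p = 2.78e-06).

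The age changes of the genotypes, which come from different arrays, correlated at 0.73 across probes. Both genotypes called 4702 probes, 4650 of them in the same direction: 2279 higher at E16.5 in both, where independent lists would share 534.9, and 2371 lower in both, where they would share 645. The ages lay on different slides with different scan days, so age and slide cannot be told apart in either genotype. The wild-type count was 2577 and 2883 without E15.5 replicate 2 or 1 and 2729 and 4538 without E16.5 replicate 2 or 1. The transgenic count was 5662 without E16.5 replicate 2, 6390 without E15.5 replicate 1, and 8054 or 8186 without the other arrays compared. With median centring the counts were 2480 and 6557. That centring moved the share of higher calls from 47.8% to 37.1% in wild type and from 47.5% to 90.3% in transgenic skin.

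**Figure D3:**
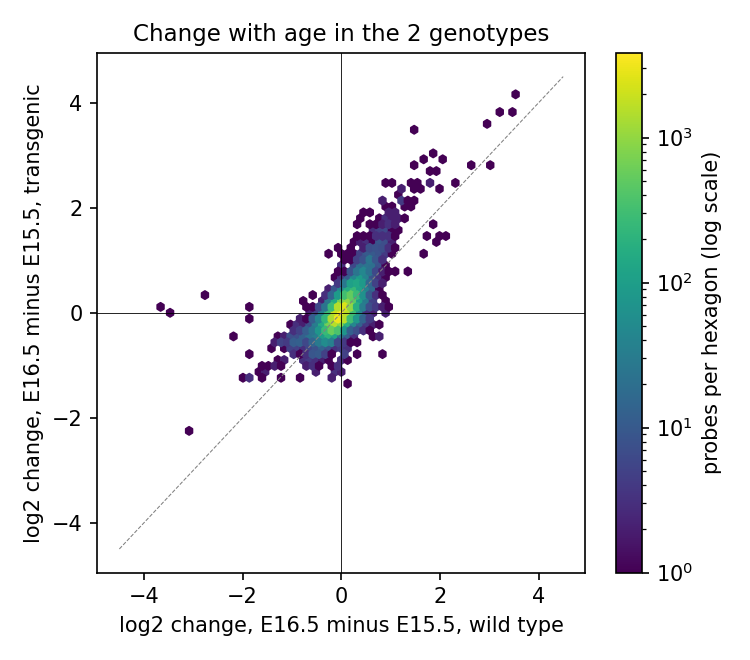
Log2 change from E15.5 to E16.5 in wild-type skin (horizontal axis) and in transgenic skin (vertical axis) for the tested probes, shaded by the number of probes per hexagon on a log scale; the dashed line marks equal changes. The changes correlate at 0.73, and the 2 highest points on both axes are Z00059773-1 and Z00041156-1.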

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

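The tests of the reference channel and of slide below were chosen after the counts were seen; those of overlapping probes and of splits were set before their results were seen.

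The transgenic effect differed between E15.5 and E16.5 for 29 probes by the test of the difference itself. The largest were Z00067181-1 (1.06) and Z00066250-1 (0.77), with a more positive effect at E16.5, and Z00054050-1 (-1.06) and Z00032151-1 (-1.05), with a more negative one. Their adjusted p-values rose to 0.192 to 0.195 at the highest over the alternatives, and the count ran from 0 to 1735, so the set is not stable.

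The counts of 1 probe at E15.5 and 4364 at E16.5 were weighed as a pattern. Noise of single probes is argued against: within 756 pairs of probes that share at least 25 bases, the E16.5 changes correlated at 0.87. With partners shuffled the value was 0.04. Both probes of a pair read the same RNA on the same arrays, so a difference between samples or slides would pass this test too. At E15.5, with 1 call, the pairs gave 0.56, so the test does not account for the gap between the counts. Cy5 alone called 46 probes and Cy3 alone 3599, of which 2336 were also called by the ratio. For those shared calls a difference in the reference channel is argued against. For the other ratio calls it is not, since Cy5 can shift a ratio without being called itself. Z00032151-1 had a called ratio at E16.5, with Cy5 alone at 0.50 (limma adjusted p = 0.157) and Cy3 alone at -0.20. Slide, scan day or handling day cannot be told apart from genotype, since 0 slides held both genotypes at E16.5. A biological difference of the transgenic skin at that age stays open beside it, untested.

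For the average over both ages, the 8 arrays can be split 4 against 4 in 35 ways, 34 of which can be fitted with age in the model. The real split called 545 probes in that model, and the highest of the others called 0, so that 1 of the 34 splits, the real one itself, gave as many. Of the 34, 18 keep 2 against 2 arrays at each age, as the real one does, which is too few for a share under 0.05. The highest other among them also called 0. Splits other than the real one leave all or part of the E16.5 difference between the genotypes in the residual spread. That lowers their counts, so the 0 calls do not show what chance gives. The real split also follows the slides at E16.5 and, at both ages, the position on the slide (transgenic at 1 and 2, wild type at 3 and 4), so neither this count nor the averaged calls separate genotype from position.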

How the results depend on the processing

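The age comparisons, the E16.5 comparison and the averaged comparison had calls in every alternative, while the E15.5 count (0 to 52) and the difference count (0 to 1735) reached 0 in some. The fits without Cy5-differing probes, with GC loess and on the series table's probes were chosen after seeing the data. Where no reason is given, the cause was not tested. Counts are given in the order E15.5, E16.5, averaged, difference, age in wild type and age in transgenic skin, for those that moved by over 1.5 times from 1, 4364, 1566, 29, 6873 and 10835.

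Agilent's processed signals gave 0, 1437, 152 and 1 for the first 4. The series table gave 0, 1276, 99, 0, 3225 and 6595 over 19315 probes; on those probes, of which fewer were tested, the main values gave 2827, 822, 17 and 4396 for E16.5, averaged, difference and age in wild type. Median centring gave 52 at E15.5, 1735 for the difference, and 2480 and 6557 for age; limma then found no spread of variances between probes (infinite prior degrees of freedom, SE 0.11 to 0.13 at E16.5), so its calls ignore how far single probes vary, and it shifted the median log2 difference of all probes to 0.11 at E16.5 and 0.15 in the difference. The share of higher calls under it was 94.9% at E16.5 (53.1% with loess), 93.5% averaged (73.8%) and 92.4% in the difference (69%). Averaged, that share was also 93.4% with Agilent's signals and 87.9% with the series table. The prior with trend and robust estimation gave 6 at E15.5, 2929 averaged and 899 for the difference. The 2-fold minimum, stricter by construction, gave 25, 6, 5, 105 and 248 from E16.5 on. The stricter filter, over 26565 probes, gave 0 at E15.5, since it removes Z00022557-1, and 132 for the difference. Cy3 alone gave 2 at E15.5 and 0 for the difference; of its 3599 E16.5 calls, 2336 were also called by the ratio. The 4 arrays alone gave 2184 at E16.5. The difference count was 57 without background correction, 0 without a filter and 0 with GC loess. Leaving out probes whose Cy5 differed removed the E15.5 call (0).

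Without 1 array, where the lone array of its group is assumed to vary like the others, the counts ran from 1 to 6 at E15.5, 732 to 3807 at E16.5, 389 to 1248 averaged, 0 to 103 for the difference, 2577 to 6473 for age in wild type and 5662 to 10880 for age in transgenic skin. At E15.5 the 6 came without transgenic replicate 2, and 2 without wild-type replicate 1.

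Over all probes, same-numbered arrays did not deviate together (correlation -0.0995 at E15.5 and -0.0215 at E16.5). This cannot show whether they shared a litter or handling, and the labels give no pairing beyond the number. Single probes went either way: Z00016441-1 was at 0.66 and 1.62 in wild type and -0.30 and 0.71 in transgenic skin at E15.5. At E16.5 it was at 2.64 and 2.41 against 0.51 and 1.39. With the replicate block the counts were 2579 at E16.5, 2392 of them called without it, and 44 for the difference; the others stayed within 1.5 times.

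Judged by sign and adjusted p, the named probes kept sign and call in 346 of 428 values, lost the call in 81 and reversed in 1. The reversal was Z00022557-1 at E16.5, 0.30 with Agilent's processed signals, where the Cy5 signal it is divided by had fallen as well. Size was not counted, so Z00060082-1 (-0.83) and Z00066250-1 (0.77) stand as kept under the 2-fold minimum, which neither reaches. The random slide effect and the gene list tests were not run, and keeping all probes per gene is the same as the main choice. Signal over background limits dim probes: 10379 probes were not tested.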

Other observations

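Protein motifs were set before their values were seen; the tests on Z00022557-1, on the probes low in wild type at E16.5 and on the age direction were chosen after, as were the motif medians under other scalings.

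Among 8 probes whose sequence encodes a carboxy-terminal stretch of histone H2A or H4, core proteins of nucleosomes, 4 were called lower at E16.5 than at E15.5 in wild type and 0 higher. The median log2 change was -0.14 (range -1.08 to 0.01; -0.08 with Cy3 alone), and camera gave an adjusted p of 0.00292 with the preset correlation (adjusted p = 0.122 with an estimated correlation). In transgenic skin 3 were called lower with age and 0 higher, and the median was -0.04 (0.22 with median centring, -0.20 with Cy3 alone, -0.11 with Agilent's signals; adjusted p = 0.282). Between the genotypes at E16.5 the median was 0.22 (0.05 with Cy3 alone, 0.38 with median centring), with 4 called higher and 0 lower in transgenic skin (adjusted p = 2.09e-05 preset, adjusted p = 0.103 estimated). At E15.5 the median was 0.09 (-0.02 with median centring) and 0 were called (adjusted p = 1.92e-05 preset, adjusted p = 0.0854 estimated). No camera test passed with the estimated correlation. The other planned set test, fry, gave adjusted p = 0.00159 and 0.0149 for age in wild type and transgenic skin. Between the genotypes it gave adjusted p = 0.0481 at E15.5 and 0.00191 at E16.5, but it does not compare the set with the other probes. Within the set 9 pairs share at least 25 bases, so the probes are not independent and may bind each other's transcripts.

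Of 15 probes that encode the linker of C2H2 zinc fingers, DNA-binding domains of transcription factors, 4 were called higher with age in wild type and 0 lower. The median change was 0.11 (0.02 with median centring or Cy3 alone), and the adjusted p was 0.025 with the preset and 0.122 with an estimated correlation. Between the genotypes at E15.5 the median was 0.03 and 0 were called (adjusted p = 0.012 preset, adjusted p = 0.0854 estimated). In transgenic skin 5 were called higher and 3 lower with age (adjusted p = 0.282). Over 7 probes that encode collagen-like Gly-X-Y repeats the median change in wild type was -0.10 while the mean was 0.07, and the camera adjusted p was 0.785. With fry the linker probes had adjusted p = 0.00543 and 0.026 for age in wild type and transgenic skin. Between the genotypes they had 0.06 at E15.5 and 0.567 at E16.5. For the collagen-like probes the fry values were 0.512, 0.00537, 0.194 and 0.00443, in the same order.

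Z00022557-1 fell with the transgene at both ages in both channels, although the reference RNA was meant to be equal on all arrays. Its Cy5 change was 7.98% of its Cy3 change at E15.5 and 7.67% at E16.5. Among 85 other probes with a Cy3 change of at least 3000 units and 1.5 log2 units and a lower Cy5 signal under 1500, the Cy5 change was -2.1% to 19.2% of it, and 27.1% of them reached 7.98%. Cy5 signal that follows Cy3 at single probes is thus a candidate explanation of the Cy5 fall, and the Cy3 fall would then be the measured one. Whether the transgenic mice lacked the transcript or differed in sequence under the probe stays open, since 0 other probes on the array share 25 bases with it.

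At E16.5, 6 probes were called with a log2 rise of at least 2 in transgenic skin, all through low wild-type arrays. Relative to the mean of the other 3 groups, wild-type replicate 1 stood at 0.32% to 2.1% and replicate 2 at 10.1% to 14.3%; in replicate 1, 3 of the 6 were not well above background, so their percentages there are imprecise, and in replicate 2 all were above it. Their median Cy5 difference was 0.01 against 2.96 for the ratio, which argues against the reference channel. The highest share in replicate 2 was 1.42 times the lowest, while over the 3 probes above background in replicate 1 it was 4.6 times the lowest, at Cy3 signals of 31.9 to 60.9 close to the floor. That the samples held different shares of embryos that express these transcripts therefore stays undecided, as does RNA carried over from another sample. The labels do not say whether embryos were pooled. Sex of the embryos was not checked, since the planned list of Y-linked genes and Xist needed gene names. Z00016441-1, set against Z00064853-1 after both were seen, ran the other way: 2.64 and 2.41 against -5.07 and -2.03 in wild-type E16.5. In every group the array with its higher ratio had the lower ratio of Z00064853-1.

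A further hypothesis, that transgenic skin at E16.5 was further along the change with age, stays undecided. The E16.5 genotype change correlated with the mean age change at 0.21 across probes, with a mean genotype change of -0.02 in the lowest and 0.10 in the highest decile of age change. At E15.5 the genotype change ran the other way, at -0.20, with a mean of -0.05 in the highest decile. The mean age change comes from the same arrays, and the genotype changes of the 2 ages differ by exactly the difference of the 2 age changes. Age changes spread more in transgenic skin (SD 0.259 against 0.208 in wild type). The slope on the mean age change must therefore be higher at E16.5 (0.17) than at E15.5 (-0.08), so these are no separate observations. Replicate arrays of one group, set against each other, gave -0.38 to 0.22, so a value of this size also arises between replicates. At E15.5 the pairs of overlapping probes correlated at 0.56 in their genotype changes, against 0 with partners shuffled. Differences too small for the test may thus exist at that age, or the arrays may differ in a way that reaches both probes of a pair.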
